A study of Mus musculus with 6 samples.

How the data were processed

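Gene expression was measured in 6 mouse samples of material the labels call MTO, an abbreviation the sources used here do not spell out, of strain C57BL/6. They comprised 3 samples that received a control guide (sgC) and 3 that received guides against Prkci and Prkcz (sgPrkci/Prkcz). Per the labels' protocols, the cells were grown in a serum-free medium with EGF and left untreated, and libraries were made from 200 ng of total RNA with a 3′ tag kit (QuantSeq FWD, with optional molecular identifiers) and read as single ends of 75 bases. A library of this kind yields tags near the 3′ end of a transcript. The labels describe culture and also injection under the skin of mice, and the design text speaks of tumors and of more replicates than the 3 per genotype listed. The deposited table is marked as in vitro, and the samples were used as their labels group them.

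The authors deposited 1 table of CPM values (reads per 1000000 reads assigned to genes) for 20756 genes, named by Ensembl identifier, and every column sums to 1000000. The genome build was GRCm38, per the submitters' processing notes. The aligner, the counter, the strand setting and the use of the molecular identifiers are not given in the sources used here. Each column was matched to a sample by its title, and 0 other columns of values were present. Symbols and coordinates came from a GENCODE annotation of GRCm38, in which 20675 identifiers had a symbol. A total of 1904 genes were at 0 in every sample.

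Within a library the deposited CPM values were whole multiples of the smallest value above 0, to a relative tolerance of 1e-06, for 100% of the values. Whole reads were therefore recovered. The totals were 2982916, 3048170 and 2821908 reads for sgC replicates 1 to 3, and 1760243, 1808292 and 1543826 for sgPrkci/Prkcz replicates 1 to 3. One read was worth between 0.328 and 0.648 CPM. A count of 0 over a group (floor of 3 reads) allowed up to 0.339 CPM in sgC and 0.587 CPM in sgPrkci/Prkcz. Floors and 95% intervals (exact, on the ratio of pooled reads) cover counting error only. Replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom of 1.56 to 3.40 over genes with at least 20 reads, so no pair was treated as a single library.

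The planned test was the edgeR quasi-likelihood test, which assumed raw counts. Because the table holds CPM, the fallback fixed with it was used: limma with a mean-variance trend and robust estimation on log2(CPM + 1), over genes with at least 1 CPM in at least 3 samples, all 6 samples and genotype as the single factor. Calls used a Benjamini-Hochberg adjusted p under 0.05, with a second count at an absolute log2 fold change of at least 1. Fold changes are sgPrkci/Prkcz minus sgC on the log2(CPM + 1) scale, which understates the change of low genes. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The planned edgeR quasi-likelihood test was run on the recovered reads as an alternative. That use of recovered reads was added after the unit was known, and it called 3754 genes.

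The comparison, the test, 30 gene lists and the rule for genes named in the text were chosen before the data were examined. The rule takes the guide targets, Has1, Has2, Has3 and Cd44 for the subject of the series title, the 8 largest rises and 8 largest falls, and up to 3 members per list with the smallest adjusted p among those called. The largest changes had to pass the threshold, average at least 10 CPM, separate all samples of the groups, and carry a symbol that is not a provisional model or a pseudogene. Other genes, such as all those called where 5 or fewer members of a list were, were chosen after their values were seen. Of the lists, 27 had at least 3 tested genes and were compared with all other genes by camera (preset inter-gene correlation of 0.01, Benjamini-Hochberg over lists). The alternatives were camera with an estimated correlation and fry. By camera 12 lists were called, 1 of them also with an estimated correlation. Fry called 13 lists in 1 direction and 26 for change in either direction, and it does not compare a list with other genes.

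Alternatives for all results were quantile normalization, median centring, limma without trend, no filter, a mean of at least 5 CPM, pseudocounts of 0.1 and 5, and each sample left out. Added after the data were seen were edgeR, DESeq2 and limma-voom on recovered reads, thinning to equal depth, TMM-scaled CPM, the median change set to 0, totals without 3 rRNA-like genes, and chromosome medians removed. Removing chromosome medians took out the full median of each chromosome, which also holds the shift of all genes. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. The pipeline was tested on simulated data for this comparison with 200 changed genes. Over 12375 genes limma recovered 81% of the 100 genes changed 2-fold and 100% of the 100 changed 4-fold, and called 5 unchanged genes. With edgeR over 9885 genes the shares were 81% and 98%, with 3 unchanged genes called. The changed genes were drawn from those with a mean of at least 3 CPM in sgC, as many raised as lowered. Both simulated groups otherwise shared the sgC profile. The simulation thus held far fewer changes than the 4300 called in the data and no overall shift like the median of -0.17 there. Its rates may not carry over to the real comparison.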

Results

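Transcripts were profiled by 3′ tag sequencing in mouse MTO samples of 2 genotypes, 3 carrying a control guide (sgC) and 3 carrying guides against Prkci and Prkcz, which encode the atypical protein kinases C iota and zeta (aPKC). Values below are CPM as mean ± SD with n = 3 per genotype, and coordinates are GRCm38. Depth followed genotype: the sgC libraries held 2821908 to 3048170 reads and the sgPrkci/Prkcz libraries 1543826 to 1808292. The labels give no batch. The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 and the rRNA-like gene Gm42418 together took 21.7% ± 0.370 of reads in sgC and 23.7% ± 1.30 in sgPrkci/Prkcz. Spearman correlations across genes, which are not independent replicates, were 0.978 to 0.987 within genotypes and 0.943 to 0.949 between them. The first principal component held 63.1% of the variance and separated the genotypes.

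Of the targeted genes, Prkcz mRNA fell and Prkci mRNA showed no detectable difference. Prkci (ENSMUSG00000037643, chromosome 3, 30995747 to 31052959) stood at 54.9 ± 8.60 CPM in sgC and 54.4 ± 0.686 in sgPrkci/Prkcz, a log2 fold change of 0.00 (limma, Benjamini-Hochberg adjusted p = 0.986). Its reads were 139, 166 and 180 in sgC and 97, 98 and 83 in sgPrkci/Prkcz. Prkcz (ENSMUSG00000029053, chromosome 4, 155260129 to 155361361) was low, with 19, 17 and 14 reads in sgC and 7, 3 and 1 in sgPrkci/Prkcz. It went from 5.64 ± 0.706 to 2.09 ± 1.71 CPM, a log2 fold change of -1.24 (limma, Benjamini-Hochberg adjusted p = 0.00967), a call kept in 18 of 21 settings. It was lost without sgPrkci/Prkcz replicate 3, with limma without trend and with DESeq2, where the Benjamini-Hochberg adjusted p was highest at 0.205. The cut sites are not given in the sources used here, and a 3′ tag outside an edited exon does not check the loss of a protein.

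The question behind the comparison, from the series title, is how aPKC loss in epithelial cells relates to hyaluronan and to mesenchymal colorectal cancer. The sgPrkci/Prkcz samples carried more mRNA for inflammatory cytokine genes, the 1 list also called with an estimated correlation, and 40 of 44 tested cell cycle genes fell. Chemokine Cxcl5 and cytokine Il1a were among the 8 largest rises, and keratins Krt90 and Krt4 among the 8 largest falls. Of 12207 genes tested with limma, 4300 changed, of which 1391 rose and 2909 fell, and 1238 changed by at least 1 on the log2 scale (383 rose and 855 fell). The median log2 fold change of all tested genes was -0.17. With that median set to 0 the split was 2125 risen and 1756 fallen, with quantile normalization 1869 and 1936, with median centring 2344 and 1580, and with TMM-scaled CPM 1993 and 1973. The edgeR test on recovered reads called 1962 risen and 1792 fallen genes out of 9842, including 3086 of the 3921 limma calls it tested, with 0 in the opposite direction.

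**Figure D1:**
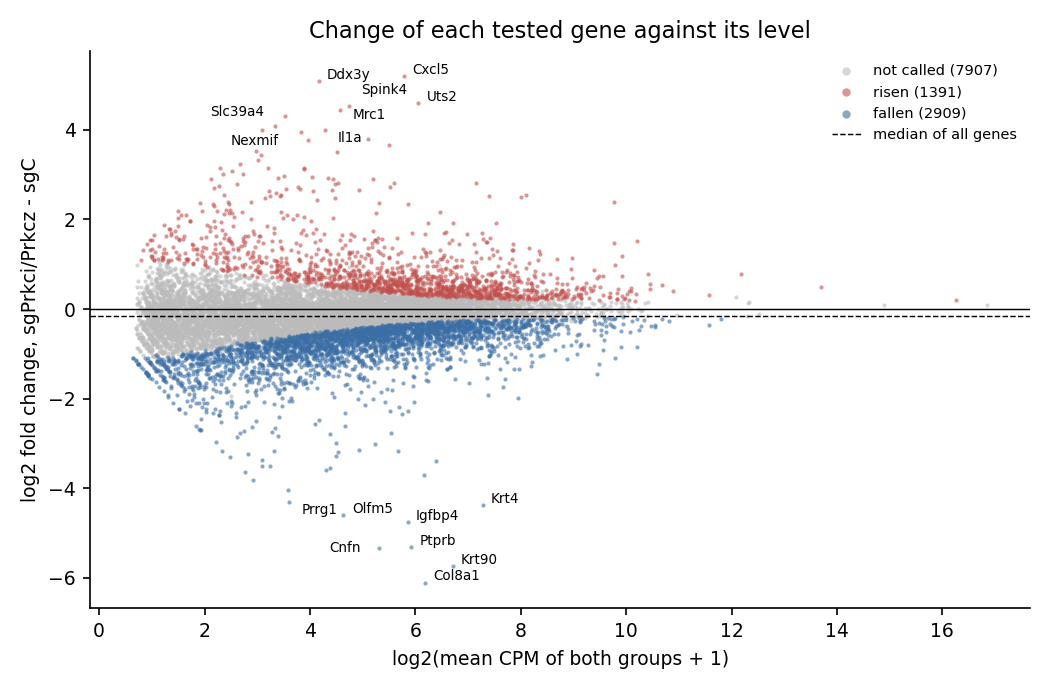
Log2 fold change (sgPrkci/Prkcz minus sgC) of each of 12207 tested genes against log2 of its mean CPM + 1. Red points are the 1391 risen genes, blue points the 2909 fallen genes and grey points the others; the dashed line at -0.17 is the median of all genes, and the 16 named genes are the largest changes under the naming rule.

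The largest rises were in secreted signals, a lectin receptor, a zinc importer and a Y-linked gene. Cxcl5 (chromosome 5, 90759360 to 90761624), which attracts neutrophils, went from 1.91 ± 0.467 to 106 ± 15.1 CPM, a log2 fold change of 5.20. Uts2, which encodes the vasoactive peptide urotensin, went from 4.28 ± 0.558 to 127 ± 6.79 CPM (4.6), and Spink4, a protease inhibitor of goblet cells, from 1.24 ± 0.695 to 50.1 ± 10.4 CPM (4.53). Mrc1, the mannose receptor, rose from 1.12 ± 0.476 to 44.3 ± 2.98 CPM (4.44). Il1a rose from 1.38 ± 0.967 to 35.7 ± 7.39 CPM (4.0), and Nexmif, an X-linked neuronal gene, from 0.801 ± 0.726 to 25.7 ± 7.06 CPM (3.95). Ddx3y (chromosome Y, 1260771 to 1286629), an RNA helicase gene, had 0 reads in sgC and 175 in sgPrkci/Prkcz, at least 101-fold higher over the pooled reads. Slc39a4, the zinc importer, had 1 read against 107, a ratio of pooled CPM of 185 with a 95% counting interval of 32.6 to 7386.

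The largest falls were in keratins and a cornified envelope gene of stratified epithelium, a collagen chain and a growth factor binding protein. Col8a1, a short-chain collagen, went from 143 ± 26.1 to 1.31 ± 1.16 CPM, a log2 fold change of -6.11. On chromosome 15, Krt90 (101552356 to 101562950) fell from 204 ± 7.47 to 2.94 ± 1.11 CPM (-5.75) and Krt4 (101918535 to 101924735) from 295 ± 11.8 to 13.4 ± 2.77 CPM (-4.38), and tags may be shared within this gene family. Cnfn, the envelope gene, fell from 76.2 ± 13.0 to 0.958 ± 0.608 CPM (-5.33). Ptprb, a receptor phosphatase, fell from 117 ± 3.15 to 1.95 ± 0.254 CPM (-5.33), Igfbp4 from 111 ± 6.80 to 3.20 ± 1.20 CPM (-4.77) and Olfm5 from 46.7 ± 9.82 to 1.02 ± 0.798 CPM (-4.61). Prrg1 had 195 reads against 1, and its ratio of pooled CPM, sgC over sgPrkci/Prkcz, was 113 with a 95% counting interval of 20 to 4470. The 16 genes of both groups stayed past the threshold, in the same direction, in every alternative that tested them.

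Among hyaluronan genes, Cd44 and 2 genes of hyaluronan precursor synthesis rose. Genes for hyaluronan breakdown went both ways, as Cemip rose and the hyaluronidase gene Cemip2 fell. Cd44 (chromosome 2, 102811141 to 102901665), the main hyaluronan receptor, went from 1006 ± 132 to 1732 ± 159 CPM, a log2 fold change of 0.79 (limma, Benjamini-Hochberg adjusted p = 3.11e-08). Gfpt1, which starts the hexosamine pathway, rose from 251 ± 19.5 to 434 ± 14.4 CPM (0.79), and Uap1, which makes UDP-N-acetylglucosamine, from 77.6 ± 5.68 to 152 ± 11.2 CPM (0.97). Cemip (1.28) rose too. Cemip2 fell from 168 ± 11.8 to 74.6 ± 8.41 CPM (-1.16), and Habp4 (-0.82) and Hmmr (-0.78) fell. The synthase Has3 had 2 reads in sgC and 1 in sgPrkci/Prkcz, at or under the floor in both, and Has1 and Has2 were not analysed here. Of 18 tested members of the hyaluronan list 4 rose and 3 fell, and 5 and 3 did when adjusted over the list alone (camera with Benjamini-Hochberg, adjusted p = 0.134).

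Polarity genes changed both ways. The falls of the scaffolds Pard3 (-0.38) and Scrib (-0.61) were lost with the median change set to 0 (limma, Benjamini-Hochberg adjusted p = 0.115 and 0.0579), and that of Pard3 also with edgeR (Benjamini-Hochberg adjusted p = 0.0724). Of 23 tested genes of aPKC and polarity complexes, 3 rose (Mpp5, 0.55; Dlg3, 0.35; Cdc42, 0.31) and 7 fell, the same numbers when adjusted over the list alone. With the median change set to 0 the numbers were 5 and 5. Besides Prkcz, the falls were smallest in adjusted p for Ect2, a guanine exchange factor (118 ± 14.6 to 59.2 ± 5.63 CPM, -0.98), Wwc1, an aPKC-binding scaffold (223 ± 4.44 to 126 ± 12.4 CPM, -0.82), and Sqstm1, an autophagy adaptor that binds aPKC (382 ± 12.4 to 225 ± 20.1 CPM, -0.76). Wwc1 and Sqstm1 lie on chromosome 11, whose genes shifted together, and with chromosome medians removed their log2 fold changes were -0.39 and -0.34. With only the median change of all genes set to 0 they were -0.65 and -0.60. The list as a whole did not stand apart from other genes (camera, Benjamini-Hochberg adjusted p = 0.621), while fry, which makes no such comparison, called it Down (adjusted p = 0.00126).

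Inflammatory NF-κB genes rose together. NF-κB is a transcription factor that induces cytokines and its own inhibitors, and among its targets Nfkbia (chromosome 12, 55489410 to 55492647) rose from 283 ± 51.6 to 1470 ± 63.7 CPM, a log2 fold change of 2.38 (limma, Benjamini-Hochberg adjusted p = 5.53e-16). The neutrophil chemokines Cxcl5, Cxcl1, Cxcl2 and Cxcl3, the cytokines Il1a and Tnf, and the feedback gene Tnfaip3 were among the 12 of 21 tested members that rose. With limma 0 members fell, 0 at an unadjusted p under 0.05 and 0 by edgeR, and 13 rose when adjusted over the list alone. The list rose against all other genes (camera, Benjamini-Hochberg adjusted p = 5.57e-12). It alone of the called lists was also called by camera with an estimated correlation (adjusted p = 0.0366). That estimate was below 0 here (-0.038). It was also below 0 for the tyrosine kinase (-0.017), gastric (-0.0067), lipid synthesis (-0.0045) and macrophage (-0.21) lists, which lost their calls. Losing the call in those lists is therefore no sign of correlated members. Tyrosine kinase and MAPK feedback genes rose in 12 of 29 cases (12 adjusted over the list alone), with Ier3 from 615 ± 85.7 to 1741 ± 8.75 CPM (1.51), Tgfa from 52.6 ± 8.51 to 93.8 ± 12.5 CPM (0.83) and Junb from 240 ± 10.2 to 324 ± 16.5 CPM (0.43). With the median change set to 0 the numbers were 16 risen and 1 fallen. The 3 that fell, in both other counts, were Etv5 (-0.70), Spry1 (-0.70) and Etv4 (-0.37). By camera that list was called (Benjamini-Hochberg adjusted p = 4.95e-04; adjusted p = 0.0830 with an estimated correlation).

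**Figure D2:**
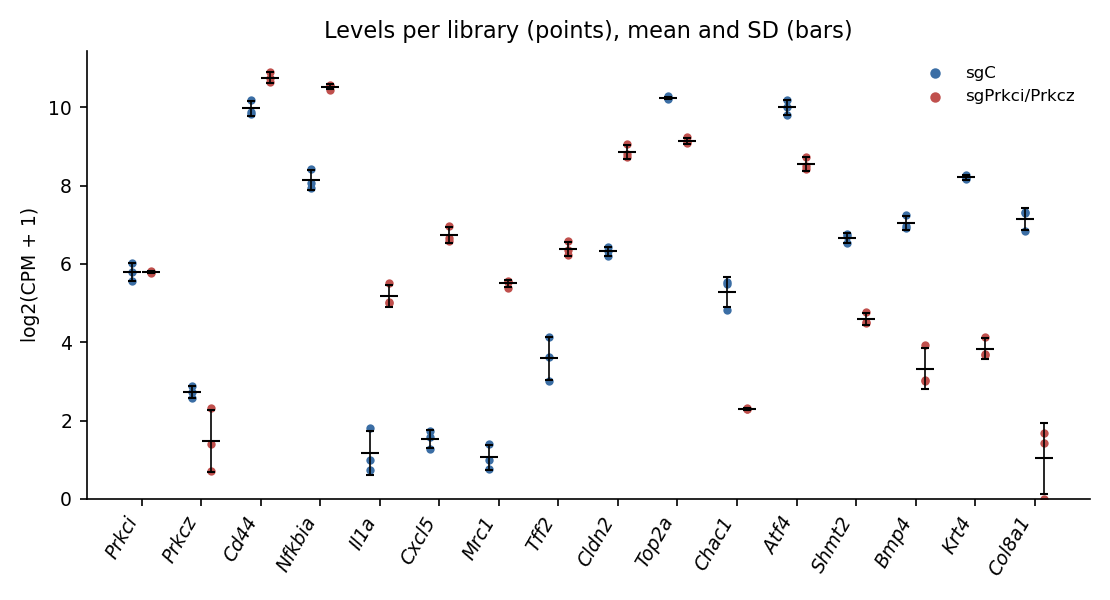
Log2(CPM + 1) of 16 genes in each library, sgC in blue and sgPrkci/Prkcz in red, with the mean and SD of each genotype as bars. Prkci did not separate the genotypes (log2 fold change 0.00), Cxcl5 and Il1a rose by 5.20 and 4.0, and Krt4 and Col8a1 lay lower by log2 fold changes of -4.38 and -6.11.

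Cell cycle genes fell almost as a block, from DNA replication (Mcm2, Mcm7, Gins2, Cdc6) to mitosis (Aurkb, Cenpe, Prc1). Top2a, the topoisomerase of dividing cells, went from 1204 ± 30.9 to 565 ± 31.7 CPM, a log2 fold change of -1.09 (limma, Benjamini-Hochberg adjusted p = 6.1e-13). Cenpe, a kinetochore motor, went from 442 ± 25.4 to 214 ± 16 CPM (-1.04) and Prc1, a spindle midzone protein, from 254 ± 11.3 to 125 ± 6.17 CPM (-1.02). Of 44 tested proliferation genes 40 fell (41 adjusted over the list alone) and, with limma, 0 rose, 0 at an unadjusted p under 0.05 and 0 by edgeR. With the median change set to 0, 35 still fell. The list fell against all other genes (camera, Benjamini-Hochberg adjusted p = 1.75e-14; adjusted p = 0.176 with an estimated correlation, which was 0.228). Targets of p53 and arrest genes split evenly, 6 risen and 6 fallen of 24, also when adjusted over the list alone, and 7 and 3 with the median change set to 0. Pmaip1, a pro-apoptotic gene, rose from 71.2 ± 5.06 to 235 ± 16.5 CPM (1.71), and Btg2, an antiproliferative gene, from 27.7 ± 0.447 to 92.2 ± 7.48 CPM (1.70), while the stress cytokine Gdf15 fell from 113 ± 26.7 to 36.2 ± 6.46 CPM (-1.60). That list was not called (camera, Benjamini-Hochberg adjusted p = 0.134), except with DESeq2 (adjusted p = 0.0183).

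Some claudin, cadherin and trefoil factor genes of gut epithelium rose. Cldn2, a pore-forming claudin, rose from 79.2 ± 6.27 to 466 ± 59.8 CPM, a log2 fold change of 2.54 (limma, Benjamini-Hochberg adjusted p = 6.84e-18). Cdh17, the intestinal cadherin, rose from 75.4 ± 9.80 to 434 ± 63.6 CPM (2.51), and Elf3, an epithelial transcription factor, from 159 ± 15.7 to 312 ± 50.9 CPM (0.95). Of 41 tested epithelial genes 15 rose and 8 fell (15 and 9 adjusted over the list alone; 19 and 4 with the median change set to 0), and the intestinal transcription factor Cdx2 was among the fallen (-1.03). Gastric-type genes showed 6 rises and 2 falls among 13 (7 and 2 adjusted over the list alone). They included Vsig1, a gastric junction protein (4.21 ± 1.35 to 37.1 ± 1.81 CPM, 2.90), and the neighbouring trefoil factor genes on chromosome 17, Tff2 (31141049 to 31144282; 11.6 ± 4.69 to 83.2 ± 10.7 CPM, 2.80) and Tff1 (31161395 to 31165277; 563 ± 32.4 to 943 ± 13.5 CPM, 0.75). Msln (-1.03) and Psca (-0.58) fell. Both lists were called (camera, Benjamini-Hochberg adjusted p = 5.26e-04 for each). The gastric call was lost without sgPrkci/Prkcz replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.0944), without replicate 3 (0.0505) and with a mean of at least 5 CPM (0.0504). With an estimated correlation the epithelial list had an adjusted p = 0.176 and the gastric list an adjusted p = 0.0830.

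Stem cell and differentiation markers moved in both directions. The stem cell genes Prom1 (11 ± 1.42 to 79.0 ± 5.89 CPM, 2.74), Lgr5 and Ephb2 rose, while the Wnt feedback genes Nkd1 (71.8 ± 3.12 to 19.9 ± 1.11 CPM, -1.80) and Axin2 fell. Of 26 Wnt and stem cell genes 9 rose and 5 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0496; adjusted p = 0.375 with an estimated correlation). Its median log2 fold change of -0.05 and mean of 0.16 differed in sign, and the call was lost in 19 alternatives. Enterocyte markers included 3 that rose, Krt20 (2.59), Vil1 (55.6 ± 3.28 to 109 ± 5.66 CPM, 0.97) and Slc26a2 (0.48), and 4 that fell, Apoa1 (-2.53), Phgr1 (6.88 ± 2.42 to 0.737 ± 1.28 CPM, -2.37), Cdhr2 (15.8 ± 4.36 to 5.49 ± 0.360 CPM, -1.34) and Car2 (-1.20), of 8 tested, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.997). Most Apoa1 reads lay in sgC replicate 1, with 48 reads against 5 in replicate 2, and Krt20 was also over 3 times as high in sgC replicate 1 as in replicate 2, so its fold depends on that library. Among 7 secretory genes Spink4, Agr2 (3.49 ± 0.676 to 18.1 ± 1.79 CPM, 2.09) and Klf4 (0.23) rose and Mmp7 fell (20.7 ± 2.97 to 12 ± 2 CPM, -0.74), the same 3 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0814). Fetal-like and YAP target genes gave 9 rises and 9 falls of 32 (10 and 9 adjusted over the list alone; 11 and 7 with the median change set to 0), with Anxa2 rising from 3421 ± 113 to 5913 ± 413 CPM (0.79), Clu from 54.7 ± 6.76 to 114 ± 9.89 CPM (1.04), and Amotl2 falling from 34.0 ± 3.73 to 7.98 ± 0.749 CPM (-1.96). The Mmp7 call was lost with quantile normalization, without sgC replicate 3 and with DESeq2 (Benjamini-Hochberg adjusted p = 0.0551, 0.0535 and 0.159). The secretory list was called without sgC replicate 1, sgC replicate 3 or sgPrkci/Prkcz replicate 2, and with edgeR and fry (Benjamini-Hochberg adjusted p = 0.0110, 0.0238, 0.0410, 0.00413 and 0.00281). The median log2 fold change of the secretory list was -0.09 and its mean 0.73. The fetal-like list was not called (camera, Benjamini-Hochberg adjusted p = 0.389).

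Most mesenchymal genes of the list were either absent from the table or too low to test. The bone morphogenetic protein ligands changed in opposite directions. Of 40 mesenchymal genes in the fixed list 27 were in the table and 12 were tested: 2 rose, among them Cd44, and Pmepa1 (128 ± 8.09 to 75 ± 6.33 CPM, -0.76), Lgals1 (562 ± 40.2 to 389 ± 33.2 CPM, -0.53) and Tpm1 (-0.32) fell, the same 2 and 3 when adjusted over the list alone and 4 and 2 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.745). The Tpm1 call was lost with the median change set to 0 and with edgeR. The Lgals1 call was lost with chromosome medians removed (-0.16; limma, Benjamini-Hochberg adjusted p = 0.151). It was kept with the median change set to 0 (-0.36; limma, Benjamini-Hochberg adjusted p = 8.88e-04). Bmp4 fell from 132 ± 16.7 to 9.51 ± 4.07 CPM, a log2 fold change of -3.72 (limma, Benjamini-Hochberg adjusted p = 1.88e-13), and Id3, a BMP target, from 81.1 ± 10.7 to 25.5 ± 5.42 CPM (-1.64), while Bmp2 rose from 20 ± 3.03 to 60.5 ± 2.50 CPM (1.56). In the TGF-β list 8 of 26 rose and 6 fell, also when adjusted over the list alone, and 9 and 4 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.298). Matrix genes gave 8 rises and 8 falls of 28 (9 and 9 adjusted over the list alone; 11 and 6 with the median change set to 0; camera, Benjamini-Hochberg adjusted p = 0.389). The basement membrane chain Col4a5 rose from 19.4 ± 4.70 to 55.6 ± 3.08 CPM (1.49), the protease inhibitor Timp2 fell from 325 ± 13.8 to 179 ± 17.0 CPM (-0.86), and the collagen receptor Itga2 had 2 reads against 47, a ratio of pooled CPM of 40.7 with a 95% counting interval of 10.7 to 346.

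The stress response transcription factor gene Atf4 and its target Chac1 fell. Atf4 (chromosome 15, 80255184 to 80257541), which drives the integrated stress response, went from 1025 ± 131 to 375 ± 44.4 CPM, a log2 fold change of -1.45 (limma, Benjamini-Hochberg adjusted p = 3.1e-12). Chac1, which degrades glutathione, went from 38.9 ± 9.91 to 3.91 ± 0.0571 CPM (-2.99), and Shmt2, a mitochondrial serine enzyme, from 101 ± 8.19 to 23.2 ± 2.51 CPM (-2.07). Of 34 stress response genes 2 rose, Xbp1 (0.42) and Pdia6 (0.37), and 15 fell (2 and 16 adjusted over the list alone). With the median change set to 0, 4 rose and 8 fell. The list was called (camera, Benjamini-Hochberg adjusted p = 0.00886; adjusted p = 0.414 with an estimated correlation). Its call was lost with median centring, limma without trend, limma-voom and TMM-scaled CPM (Benjamini-Hochberg adjusted p = 0.0664, 0.0911, 0.0531 and 0.0530). Glutathione synthesis genes fell as well: Gclc from 278 ± 15.6 to 109 ± 6.49 CPM (-1.34) and Gclm from 232 ± 4.49 to 99.2 ± 2.43 CPM (-1.22). Gsta3, whose tags may be shared with related transferase genes, rose from 31.9 ± 7.60 to 143 ± 6.66 CPM (2.16), along with Gstp1 (1.34), Prdx6 (0.61) and Gpx2 (0.60). In all 4 NRF2 target and glutathione genes rose and 10 fell of 31, also when adjusted over the list alone, and 7 and 10 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.319; fry, Down, adjusted p = 0.0109).

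Many hypoxia and glycolysis genes and several sterol genes rose. Egln3, an oxygen-sensing hydroxylase, went from 463 ± 1.16 to 1282 ± 61.7 CPM, a log2 fold change of 1.47 (limma, Benjamini-Hochberg adjusted p = 5.9e-16), Ero1l, an oxidase of the endoplasmic reticulum, from 733 ± 25.9 to 1216 ± 45.7 CPM (0.73), and Ndrg1 from 539 ± 8.52 to 897 ± 33.7 CPM (0.73). Of 32 such genes 17 rose, and the lactate exporter Slc16a3 (-1.01) and Pfkl (-0.44) fell, the same 17 and 2 adjusted over the list alone and 21 and 1 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 9.91e-07; adjusted p = 0.0830 with an estimated correlation). The sterol genes Hmgcs1 (589 ± 29.3 to 1167 ± 42.9 CPM, 0.99) and Sc5d (222 ± 12.6 to 332 ± 8.39 CPM, 0.58) rose, while the fatty acid synthesis genes Acaca (-0.70) and Fasn (-0.32) fell. Acaca and Fasn lie on chromosome 11, whose genes shifted down together, so their falls may follow that shift. Of 31 lipid synthesis genes 14 rose and 2 fell, also when adjusted over the list alone, and 18 and 1 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 1.04e-05; adjusted p = 0.0729 with an estimated correlation). Nuclear genes of oxidative phosphorylation gave 5 rises (among them Sdhd, Sdhc, Cox8a and Ndufb3) and 8 falls of 42, also when adjusted over the list alone, and 14 and 6 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.665). Uqcrq fell from 311 ± 28.4 to 175 ± 13.4 CPM (-0.82), Ndufb9 from 128 ± 8.24 to 80.5 ± 8.20 CPM (-0.66) and Uqcrc1 from 192 ± 12.4 to 136 ± 7.77 CPM (-0.50). In the autophagy and lysosome list 7 of 35 rose, including the protease Ctsd (145 ± 11.4 to 220 ± 6.63 CPM, 0.61) and Map1lc3a (20.7 ± 1.40 to 34.7 ± 1.95 CPM, 0.72), and 3 fell, among them Sqstm1 and Becn1 (-0.36), also when adjusted over the list alone, and 12 and 1 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.0814). It was called with median centring, DESeq2, TMM-scaled CPM, the median change set to 0 and chromosome medians removed (Benjamini-Hochberg adjusted p = 0.0311, 0.0192, 0.0365, 0.0374 and 0.00387).

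Interferon genes were mixed, and 3 of 12 tested antigen presentation genes rose. Isg20, an exonuclease (43.9 ± 5.99 to 86.7 ± 15.2 CPM, 0.96), and Ifngr2, an interferon gamma receptor chain (26.6 ± 2.78 to 52.5 ± 7.72 CPM, 0.95), rose with Mx1 and Gbp7, and the ubiquitin-like modifier Isg15 fell from 5.17 ± 1.12 to 0.963 ± 0.274 CPM (-1.64). In all 4 of 24 interferon genes rose and 6 fell, also when adjusted over the list alone, and 8 and 5 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.389). H2-D1 (210 ± 21 to 275 ± 14.3 CPM, 0.39), H2-K1 (362 ± 14.4 to 449 ± 8.20 CPM, 0.31) and the peptide loading gene Tapbp (46.1 ± 9.96 to 67.0 ± 11.4 CPM, 0.54) rose. The first pair are near-identical genes whose tags may be shared. These were 3 of 12 tested genes (5 with the median change set to 0), also adjusted over the list alone, and with limma 0 fell, 0 at an unadjusted p under 0.05 and 0 by edgeR (camera, Benjamini-Hochberg adjusted p = 0.0333; adjusted p = 0.239 with an estimated correlation). The list call was lost in 10 alternatives. With limma without trend the calls of H2-D1, H2-K1 and Tapbp were lost (Benjamini-Hochberg adjusted p = 0.0702, 0.0874 and 0.0997), and that of Tapbp also without sgC replicate 2 (0.0558).

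**Figure D3:**
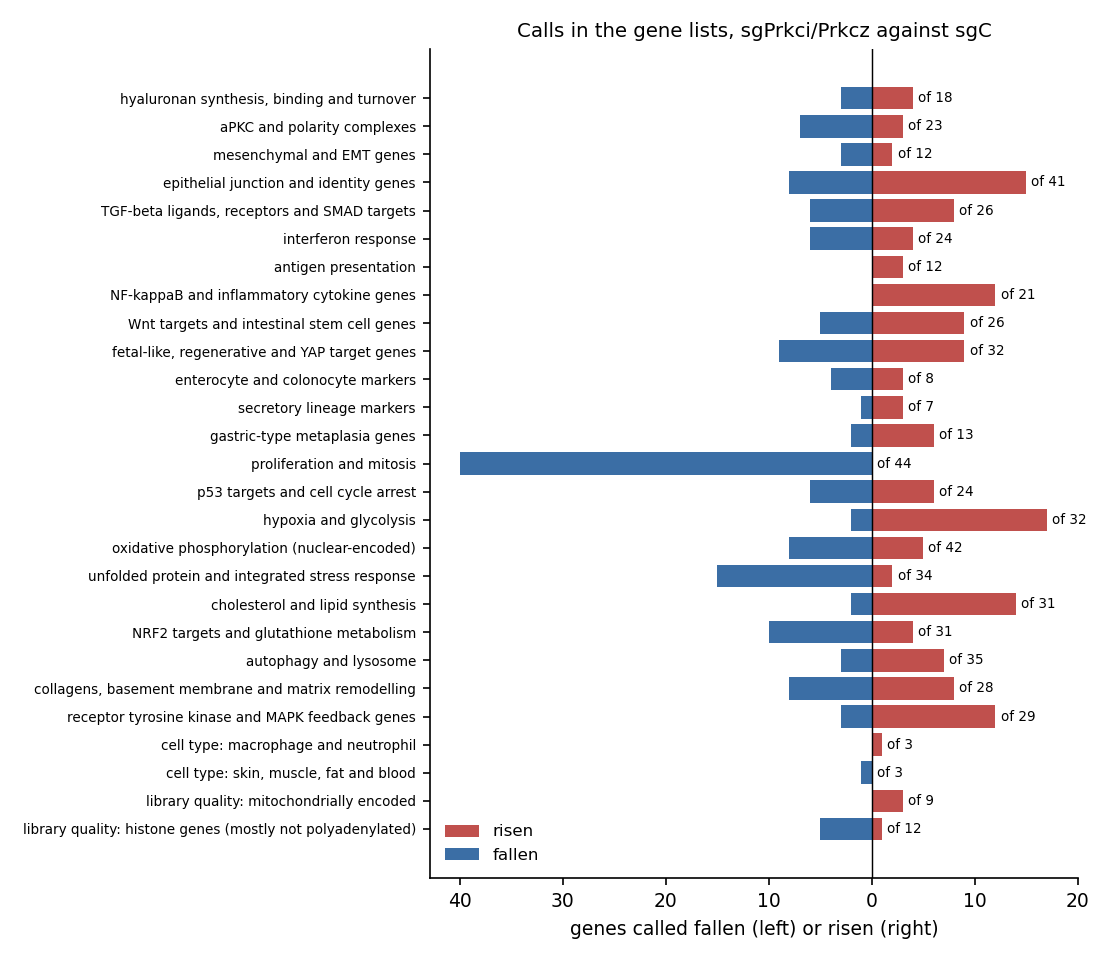
Genes called fallen (blue, to the left) and risen (red, to the right) in each of the 27 lists with at least 3 tested genes; the number after each bar is the genes tested. Proliferation had 40 falls and 0 rises of 44, and the NF-κB list 12 rises and 0 falls of 21.

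In the mesenchymal, interferon, fetal-like, matrix and oxidative phosphorylation lists the median and mean log2 fold change were below 0 while camera placed the list above other genes.

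Most markers of other cell types in the table were too low to test. Fibroblast markers, among them Pdgfra and Col6a3, summed to 1.36 ± 1.01 CPM in sgC and 1.59 ± 0.913 in sgPrkci/Prkcz, and 0 of 8 in the table passed the filter. Of 3 tested macrophage and neutrophil markers 1 rose, Mrc1, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0154; adjusted p = 0.176 with an estimated correlation). The list call was lost with no filter, DESeq2 and limma-voom (Benjamini-Hochberg adjusted p = 0.0590, 0.0732 and 0.0701). The endothelial and mural markers Flt1 (37.7 ± 5.40 to 75.3 ± 4.75 CPM, 0.99) and Notch3 (10.3 ± 1.96 to 18.1 ± 3.84 CPM, 0.75), the 2 tested in their list, rose, also adjusted over the list alone. The Notch3 call was lost without sgC replicate 2 and without sgPrkci/Prkcz replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.0685 and 0.0530). Among 2 tested lymphocyte markers the immunoglobulin gene Igkc fell, also adjusted over the list alone, with 73, 5 and 13 reads in sgC and 0 in sgPrkci/Prkcz, at least 17.5-fold lower. That bound rests on sgC replicate 1, which held 73 of the 91 reads, and no call could be tested without an sgC replicate, since the filter then removed the gene. Its call was lost without sgPrkci/Prkcz replicate 3 and with a pseudocount of 5, with a highest adjusted p of 0.182 (limma, Benjamini-Hochberg). The basal keratin Krt14 fell from 91.0 ± 10.1 to 9.18 ± 0.723 CPM (-3.17), the 1 call among 3 tested skin, muscle, fat and blood markers, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.388; fry, Down, adjusted p = 0.00137). The median log2 fold change of these 3 was 0.14 and their mean -0.84.

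Mitochondrially encoded and histone genes were listed as a check of the libraries. Of 9 tested mitochondrial genes 3 rose (7 with the median change set to 0 and 8 by edgeR), also adjusted over the list alone: mt-Rnr2 (log2 fold change 0.19), mt-Cytb (2711 ± 59.5 to 3371 ± 354 CPM, 0.31) and mt-Nd6 (36.0 ± 3.04 to 53.7 ± 9.24 CPM, 0.56). The mt-Rnr2 change was 0.00 with quantile normalization, and its call was also lost with limma without trend and without sgPrkci/Prkcz replicate 1 (limma, Benjamini-Hochberg adjusted p = 0.257 and 0.0614), that of mt-Cytb with limma without trend (0.123). With limma 0 fell, 0 at an unadjusted p under 0.05 and 0 by edgeR (camera, Benjamini-Hochberg adjusted p = 0.00817; adjusted p = 0.458 with an estimated correlation). The list call was lost with quantile normalization, without sgPrkci/Prkcz replicate 3 and with fry (Benjamini-Hochberg adjusted p = 0.119, 0.0561 and 0.163). The linker histone gene Hist1h1c rose from 85.1 ± 3.15 to 243 ± 21.7 CPM (1.5). H2afz (114 ± 10.9 to 68.7 ± 0.477 CPM, -0.72), Hist1h1e (171 ± 15.5 to 121 ± 13.7 CPM, -0.50), Hist1h2ae (-1.12), Hist1h1b (-0.87) and H2afx (-0.39) fell, 5 of 12 tested (6 adjusted over the list alone; 2 risen and 3 fallen with the median change set to 0; camera, Benjamini-Hochberg adjusted p = 0.389).

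Change also followed chromosomes, so that the direction of many genes went with their position. Over genes with a mean of at least 10 CPM, the median log2 fold change minus that of all genes was 0.29 on chromosome 1, where 174 genes rose and 61 fell. It was -0.30 on chromosome 11, where 23 rose and 361 fell, and -0.25 on chromosomes 8 and 15. Top2a, Igfbp4, Sqstm1, Wwc1, Timp2, Uqcrq and Krt14 are some of the falls named above that lie on chromosome 11. Among rises named above, Uap1, Elf3, Vil1, Btg2 and Gsta3 lie on chromosome 1. With chromosome medians removed the log2 fold changes were smaller, at -0.66 for Top2a, -0.34 for Sqstm1, -0.39 for Wwc1, -0.44 for Timp2 and -0.40 for Uqcrq. On chromosome 15 they were -1.07 for Atf4 and -0.29 for Ndufb9, and on chromosome 1 they were 0.80 for Uap1, 0.79 for Elf3, 0.80 for Vil1 and 1.53 for Btg2. They were larger for Ndrg1 (1.10) and Junb (0.80), on chromosomes 15 and 8. The median removed was the full one of each chromosome, which also holds the negative shift of all genes. With only the median change of all genes set to 0, log2 fold changes were -0.92 for Top2a, -0.60 for Sqstm1 and -0.65 for Wwc1. They were then -1.28 for Atf4, 0.60 for Junb and 1.13 for Uap1. Against 10000 random gene sets matched on expression, 13 of 20 chromosomes differed at a Benjamini-Hochberg adjusted p under 0.05. The permutation p of 1e-04 for chromosomes 1, 8, 11 and 15 is the smallest these sets can give. The sets treat genes as independent and do not resample libraries, so this p does not measure the spread between samples. Some of the 13 differed little, such as chromosome 2 (-0.045). After thinning to equal depth its adjusted p was 0.226 (permutation, Benjamini-Hochberg). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 1 read in sgC and 380 in sgPrkci/Prkcz (73.7 ± 12.1 CPM), while the X-linked Eif2s3x stood at 14.8 ± 1.97 and 14.8 ± 1.80 CPM.

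**Figure D4:**
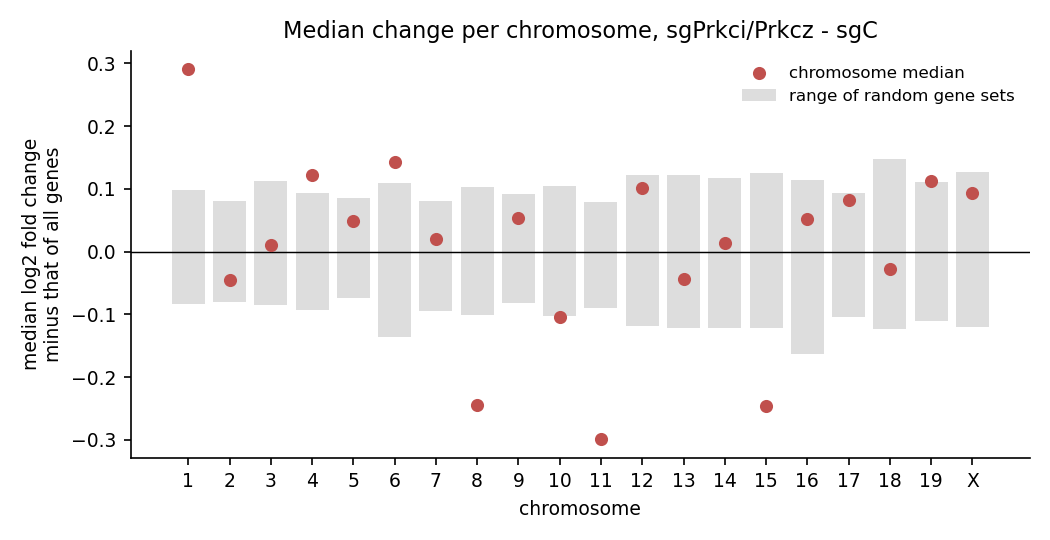
Median log2 fold change of the genes of each chromosome minus that of all genes (red points), for genes with a mean of at least 10 CPM; grey bars span the medians of 10000 random gene sets matched on expression. Chromosomes 1 (0.29), 8 (-0.25), 11 (-0.30) and 15 (-0.25) lie outside those ranges, as do chromosomes 4, 6, 10 and 19 by less.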

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

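The alternatives edgeR, DESeq2, limma-voom, thinning to equal depth, TMM-scaled CPM, the median change set to 0, totals without rRNA-like genes and chromosome medians removed were chosen after the data were seen. Of these, edgeR was the planned test, here run on recovered reads. The cause of the differences below was not tested, except where a construction shows it. No paired analysis was possible because the sample titles of the genotypes share no number. Of the other list tests 529 were the same, 51 weaker and 14 stronger, and of the other named gene tests 1877 were the same and 19 weaker. Igkc, Prkcz and other low genes have no value under filters that remove them.

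Of 1391 risen and 2909 fallen genes, median centring gave 2344 and 1580, and the median change set to 0 gave 2125 and 1756, where subtracting a negative median raises every change by construction. Fallen genes numbered 1936 with quantile normalization, 1792 with edgeR, 1690 with limma-voom, 1072 with DESeq2 and 1810 with chromosome medians removed. Risen genes numbered 909 with limma without trend. Changed genes numbered 2549 with DESeq2 against 4300. Changes of at least 1 log2 numbered 775 with a mean of at least 5 CPM and 479 with a pseudocount of 5, which shrinks changes by construction. With a library left out, 3079 to 3978 genes changed.

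Prkci, not called in the limma result, turned from 0.00 to 0.0943 with quantile normalization, 0.20 with median centring, 0.13 with edgeR, 0.14 with DESeq2, 0.14 with limma-voom, 0.0842 with thinning, 0.14 with TMM-scaled CPM, 0.16 with the median change set to 0, 0.0337 without rRNA-like genes and 0.11 with chromosome medians removed. With a library left out it ran from -0.11 to 0.11.

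List directions turned only in lists not called by camera (Benjamini-Hochberg adjusted p throughout this paragraph). For enterocyte markers the adjusted p was 0.165 with a mean of at least 5 CPM, 0.95 with a pseudocount of 0.1, 0.968 with a pseudocount of 5, 0.460 with edgeR, 0.568 with limma-voom and 0.216 to 0.905 with a library left out, where the direction turned in 5 of 6 cases, not without sgPrkci/Prkcz replicate 1. For mesenchymal genes it was 0.724 with no filter, 0.989 with DESeq2 and 0.435 with fry. For secretory markers it was 0.736 with no filter, and for polarity complexes 0.916 with chromosome medians removed. For oxidative phosphorylation it was 0.205 with fry and 0.422 to 0.906 with a library left out, where the direction turned only without sgC replicate 1 (0.906). With fry it was 0.678 for TGF-β genes, 0.253 for interferon genes and 0.290 for both fetal-like and matrix genes. Called lists that lost their call kept their direction: the Wnt list in 19 alternatives, with adjusted p up to 0.375, the antigen presentation list in 10, the stress response list in 5, and the gastric, mitochondrial and macrophage lists in 4 each. The epithelial, proliferation, hypoxia, lipid synthesis and tyrosine kinase lists lost it only by camera with an estimated correlation (adjusted p = 0.176, 0.176, 0.0830, 0.0729 and 0.0830).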

Other observations

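All tests in this section were chosen only after the result was seen, except the splits of the samples and the second list of intestinal genes. Genes of amino acid supply fell in added lists, of which the metabolic list shares Shmt2, Psat1, Asns and Phgdh with a fixed list. Aminoacyl-tRNA synthetases, which charge tRNAs, fell in 17 of 20 cases, led by Tars (-1.54), Mars (-1.50) and Lars (-1.34), with a median log2 fold change of -0.84 (camera, Benjamini-Hochberg adjusted p = 1.11e-12; adjusted p = 0.0230 with an estimated correlation). Genes of serine, glycine, proline and one-carbon metabolism fell in 17 of 20 cases, with Aldh1l2 (-2.48), Cth (-2.32), Pycr1 (-2.01), Mthfd2 (-1.92) and Psph (-1.56), and a median of -1.16 (camera, Benjamini-Hochberg adjusted p = 2.09e-12; adjusted p = 0.0230 with an estimated correlation). With the median change set to 0, 17 and 15 still fell. The p-values of the added lists were adjusted over the added lists alone, which were written after the data were seen. They are no independent tests and cannot be compared with those of the fixed lists.

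Of 14 squamous keratin and cornified envelope genes 9 fell, among them Krt90, Cnfn, Krt4, Krt14 and Dsg3, while Ivl (2.09) and Sprr1a (0.66) rose, and 7 fell with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 9.00e-05; adjusted p = 0.0994 with an estimated correlation). That list was prompted by Krt90, Krt4, Cnfn and Krt14, so its p is no independent test. Of 5 tested Hox genes 4 rose, Hoxa5, Hoxa7, Hoxa3 and Hoxa4 of 1 cluster on chromosome 6 (camera, Benjamini-Hochberg adjusted p = 7.90e-05). Of 80 ribosomal protein genes 8 rose and 21 fell, and 23 and 7 with the median change set to 0 (camera, Benjamini-Hochberg adjusted p = 0.816).

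The 6 samples can be split into groups of 3 in 10 ways, so splits cannot give a share under 0.05. The real split gave 4300 changed genes with limma, and it was 1 of the 10 splits with as many. The highest count of another split was 0 with limma, 0 with edgeR and 386 at an unadjusted p under 0.05. Each other split puts both genotypes in both groups, so the difference between genotypes widens the spread within groups. Low counts there were thus likely in advance, and the contrast with 4300 is no evidence against chance.

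Whole chromosomes shifted between the genotypes. Lower depth did not account for it: after thinning, the median change of chromosome 1 minus that of all genes was 0.32. It also did not account for the Y-linked genes, for which 658 sgC reads would be found at the sgPrkci/Prkcz rate and 1 was. A female sgC line with a retained inactive X that expresses Xist did not account for the missing Y-linked reads, since Xist reached only 0.67 CPM in an sgC library. Low Xist cannot exclude a female line without such an X, so a different origin of the lines stays open. The Xist level says nothing on the shifts of other chromosomes. On chromosome 1, 100% of 20 Mb windows had a median above 0, from 0.02 to 0.45, so its rise was spread along it. That chromosome was chosen for its shift, so windows above 0 were likely in advance. A difference in chromosome copy number between the lines may contribute to the shifts of chromosomes, which these windows cannot decide. For the shifted chromosomes the data do not show whether such a difference arose with the edit or by drift of a line. The Y-linked genes, with 1 read in sgC and 380 in sgPrkci/Prkcz, argue against a loss of the Y with the edit. Against random gene sets 13 of 20 chromosomes differed, and a difference between the lines could also act on genes elsewhere. Calls on any chromosome, not only 1, 8, 11 and 15, may therefore reflect such a difference and not aPKC loss. With chromosome medians removed 12 of 12 called lists stayed called, so the median shift of each gene's own chromosome did not account for those calls. Shifts of parts of a chromosome stay in. Chromosome 7, for example, had a median of 0.02 with windows from -0.39 to 0.19. Effects of a shifted chromosome on genes elsewhere are not removed either. Neither can be told apart from aPKC loss.

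More genes fell than rose in the limma result. Thinning left 66.1% of calls fallen and leaving rRNA-like genes out of the totals left 63.3%, so neither was the whole cause. The share was 67.7% in the limma result, 50.9% with quantile normalization, 47.7% with edgeR, 46.3% with limma-voom, 45.2% with the median change set to 0, 42.1% with DESeq2 and 40.3% with median centring, and CPM values give no absolute amounts, so the excess of falls may be a matter of scaling.

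Some transcripts typical of other cell types differed between genotypes or libraries. Macrophage RNA did not account for Mrc1, at 44.3 CPM in sgPrkci/Prkcz, because Lyz2 and C1qa had 0 reads there, an upper limit of 0.587 CPM. This test replaced a first version whose outcome had been seen: the summed CPM of measured macrophage markers other than Mrc1 reached 13.1 in a sgPrkci/Prkcz library, above the bound of 10 then set, through Cd14, which stood at 5.88 CPM in sgC as well. The change of test followed that outcome, so this exclusion is weaker than 1 planned in advance.

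Reads of 19 intestinal tissue genes, such as Reg3b, Fabp2, Sis and Igha, numbered 620, 19 and 147 in sgC replicates 1 to 3 and 4, 3 and 1 in sgPrkci/Prkcz. Carry-over of intestinal tissue RNA may contribute, but a second list, fixed before its reads were looked at, gave sgC replicate 1 over replicate 2 as 1.88, between the bounds of 1.5 and 3, so carry-over and other origins cannot be told apart by it. Its 19 genes below the filter had 45, 2 and 12 reads in sgC replicates 1 to 3 and 3, 0 and 1 in sgPrkci/Prkcz, but the filter itself picks genes low in most libraries, so this decides nothing. No difference between genes was detected in the ratio of sgC replicates 1 and 3 (permutation p = 0.809), but the genes were chosen for their shared pattern and many have few reads, so whether there was a single source stays open. Igha, Igkc and Jchain, genes of plasma cells chosen after their reads were seen, together stood at 67.0 CPM in sgC replicate 1 and at 0 in sgPrkci/Prkcz. Differentiation of epithelial cells forbids more than a trace of them, so it does not account for these 3 genes. Of 67 tested genes more than 3 times as high in sgC replicate 1 as in replicate 2, 3 were called fallen (Igkc, Apoa1 and 9530053A07Rik) and 5 risen.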
